A study of Mus musculus with 6 samples.

How the data were processed

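Transcript levels were measured in whole liver of 10-week-old male C57BL6 mice, an inbred laboratory strain. The mice had been fasted for 16 h and then received an intraperitoneal injection of saline or of 100 ng of interleukin-6 (IL-6) per mouse, and livers were taken after 1 h. IL-6 is a cytokine that signals through its receptor, the shared chain gp130 and the transcription factor STAT3. Each of the 6 arrays held 1 sample, 3 from saline and 3 from IL-6 animals. Total RNA was labelled with biotin and hybridised to 1-colour Affymetrix arrays whose probe sets each combine several probes along a transcript.

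The deposited values are log2 expression values per probe set made with RMA, per the submitters' processing notes. RMA corrects background, quantile-normalizes the arrays and summarises the probes of a probe set on the log2 scale, and its version, settings and genome build are not given in the sources used here. The deposited log2 values were used as they were. Medians of the arrays over all probe sets lay between 5.42 and 5.48, and values ran from 0.94 to 14.1. Scanner intensities were not used here, so background levels could not be assessed per probe set. This summary and the quantile normalization can compress large changes and remove a shift common to most genes, so fold values are on the scale of these arrays.

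The table held 35556 probe sets. The platform table gave exactly 1 gene symbol to 21789 of them, several to 1621, and did not list 12146, which are unnamed here. Of the probe sets with 1 symbol, 21698 were matched by gene ID to a mouse gene table on assembly GRCm38.p6, and 0 symbols changed. That table served for names, transcript types and which genes lie within each other. No coordinates are printed, because the build of the array design is not given. For 999 genes with several probe sets, the one with the highest mean over all 6 arrays was kept, which left 19938 genes. No filter on dim genes was applied.

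IL-6 was compared with saline with limma (version 3.58.1 in R 4.3.3) using lmFit and eBayes, and p-values were adjusted over 19938 genes by the Benjamini-Hochberg method with a threshold of 0.05. Tests were two-sided. Array number limits the precision: the median standard error of a log2 difference was 0.089, and an exact permutation test of 3 arrays against 3 cannot give a p under 0.1. The labels name the arrays as separate samples of each group without stating in so many words that each came from its own mouse, so p-values measure the spread between these samples. Data were also simulated with independent genes, whose variances were drawn from the distribution that limma fitted to these arrays. There the fit recovered 52% of genes changed by a log2 difference of 0.5, 98% at 1, 100% at 2 and 94% at -1. It made 7 false calls, 3.91% of calls, and 0 calls where no gene was changed. The simulation changed 50 genes at each difference, drew errors as limma's model assumes, and held no correlation between genes and no array effects. It therefore does not show how many calls on the real arrays are false, or what share of real changes is recovered there.

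There were 23 gene lists and 11 lists of cell type markers, fixed with the tests, the alternatives and the rule for named genes before the data were examined. Each list was tested with limma's camera at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over 34 lists. The test was repeated with an estimated correlation, on ranks, and with fry, whose p asks whether the members of a list move on balance one way. Lists shared members, most of all the glucocorticoid list, of whose 22 measured genes 15 also stood in another list. List symbols without a probe set of exactly 1 symbol were not analysed here.

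Named genes were the 15 called genes with the largest rise and up to 10 with the largest fall, provided that the 3 IL-6 values lay on one side of the 3 saline values. Up to 4 members of each list were added, called genes first by size and then by smallest p, together with Socs3, Stat3, Il6ra, Il6st, Hamp, Saa1, Saa2, Fgb, Pck1, G6pc, Irs1, Irs2, Ppargc1a, Igfbp1, Cyp7a1 and Alb. Outside this rule, Saa4, Fga, Serpina3n, Socs2, Pim3, Jun, Btg2, Junb and Atf3 are given as further called members of their lists. Other genes outside it are said to be so where they appear, or stand in checks stated to be made afterwards.

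Other settings fixed beforehand were median centring, cyclic loess, a repeated quantile normalization, removal of genes below the 25th percentile or below the median of level, the mean of a gene's probe sets, every probe set, a variance prior with a trend with and without robust fitting, array weights, the replicate number as a block, other thresholds, and leaving out each array. After seeing the data, 3 more were added, 2 that tested more probe sets and 1 that left out the 2 arrays set apart by the second principal component. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.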

Results

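The data were 6 arrays of mouse liver, 3 taken 1 h after saline and 3 taken 1 h after IL-6. The comparison asks which liver transcripts differ after a short exposure to IL-6 in fasted animals. Over all 35556 probe sets, Pearson correlations between arrays of a group ran from 0.989 to 0.991 and those between groups from 0.987 to 0.990. Over 19938 genes, the first principal component held 31.6% of the variance and placed the 3 saline arrays on one side and the 3 IL-6 arrays on the other. The second held 23.1% and set saline replicate 2 (-11.6) and IL-6 replicate 3 (-13.15) apart from the other 4 arrays (1.83 to 9.65). The labels name no batch. Without those 2 arrays, a comparison of 2 against 2 chosen after seeing the data, limma called 31 higher and 2 lower genes, all among the 84 called with 6 arrays.

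One hour after IL-6, members of the acute-phase, JAK-STAT signalling and feedback, and immediate-early lists rose, and few transcripts were lower. The largest rises were in Saa2 and Saa1, serum amyloid A proteins of the acute phase, at 20.1-fold and 14.3-fold. Steap4, a metalloreductase, rose 9.36-fold, Cxcl1, a chemokine that attracts neutrophils, 9.30-fold, and Socs3, an inhibitor of JAK-STAT signalling, 8.86-fold. In limma, 77 genes rose and 7 fell at adjusted p under 0.05, each with n = 3 arrays per group. In all 84 the groups did not overlap, as held for 11.6% of all genes, where chance gives 10%. The call itself nearly requires this in the called genes, so it is no further support for them.

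Saa2 (probe set 10553274) went from 6.44 ± 0.30 to 10.77 ± 0.32 on the log2 scale (SD, n = 3 in each group), a log2 difference of 4.33 ± 0.18 (standard error, limma adjusted p = 4.37e-06). Saa1 (10563611) went from 5.04 ± 0.64 to 8.88 ± 0.30, a difference of 3.84 ± 0.28 (limma adjusted p = 0.000277). Saa1 and Saa2 are close relatives in sequence, and cross-hybridisation between their probe sets was not tested. Steap4 rose by 3.23 ± 0.12 (limma adjusted p = 1.45e-06) and Cxcl1 by 3.22 ± 0.09 (limma adjusted p = 4.32e-07). Socs3 rose by 3.15 ± 0.11, and its other probe set by 1.79. The DNA damage and stress genes Gadd45a and Gadd45g rose by 2.64 ± 0.09 and 2.37 ± 0.18, the acute-phase gene Orm2 by 2.44 ± 0.23, and Lcn2, an iron-siderophore-binding protein, by 1.72 ± 0.22. Next came Phlda1 at 1.65 ± 0.15, the interferon-inducible Mx2 at 1.61 ± 0.13, the serpin Serpina10 at 1.60 ± 0.10, the kinase Pim1 at 1.52 ± 0.08, Osgin1 at 1.45 ± 0.11, and Zfp36, which promotes the decay of cytokine mRNAs, at 1.43 ± 0.09. Of the 77 higher genes, 32 rose at least 2-fold and 8 at least 4-fold, and their median log2 difference was 0.95.

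The 7 lower genes changed less. Kcnk5, a potassium channel, fell by 1.37 ± 0.17 on the log2 scale and G0s2, an inhibitor of the lipase ATGL, fell by 1.09 ± 0.17, the lower genes that reached 2-fold (limma adjusted p = 0.00772 and 0.0308). Map2k6, a kinase that activates p38, fell by 0.90 ± 0.09, Spata2l fell by 0.71 ± 0.11, 2900005J15Rik fell by 0.66 ± 0.08 and Serpina9 fell by 0.47 ± 0.08. The call of G0s2 was lost on leaving out any array but IL-6 replicate 3 (limma adjusted p up to 0.131), that of Serpina9 on leaving out any array (up to 0.195), and that of Kcnk5 without IL-6 replicate 3 (0.0569). That of Spata2l was lost without saline replicate 3 or any IL-6 array (limma adjusted p up to 0.168). Map2k6 and 2900005J15Rik kept their calls whichever array was left out. Olfr960, an olfactory receptor gene, fell by 0.67 ± 0.11 at a saline level of 3.14, below the 25th percentile of all genes (4.59), where differences are hard to separate from background, and its call was lost on leaving out any array but IL-6 replicate 2 (limma adjusted p up to 0.234).

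**Figure D1:**
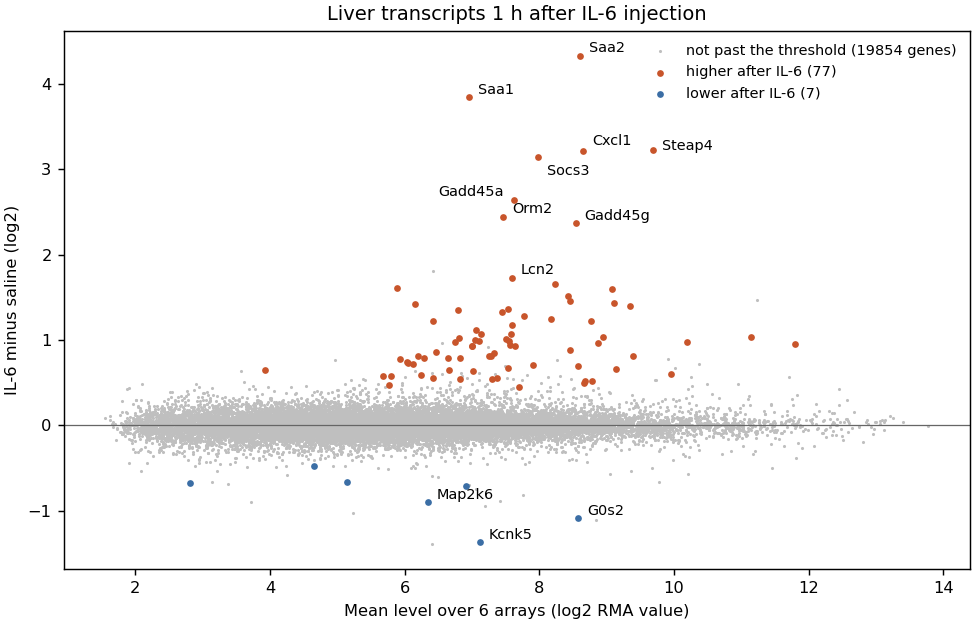
Log2 difference, IL-6 minus saline, against the mean log2 RMA value over 6 arrays, with each point a gene. The 77 higher genes reach 4.33 and the 7 lower genes reach -1.37, while the median over all genes is 0.003.

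**Figure D2:**
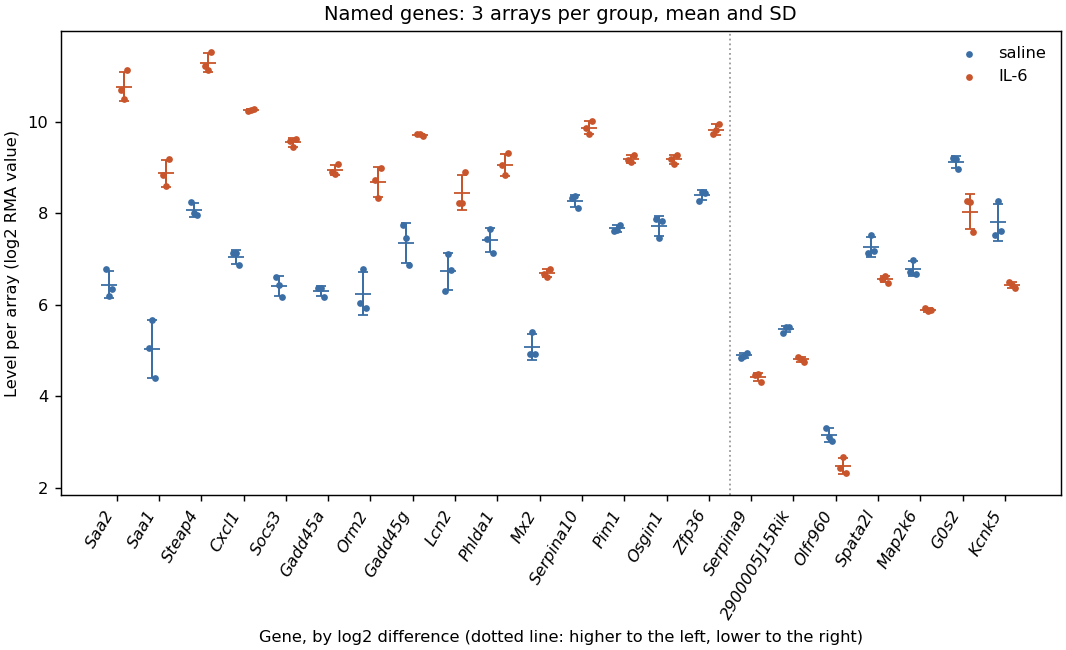
Log2 RMA value per array for the 15 genes with the largest rise and the 7 lower genes, with points for single arrays and bars for the mean and SD of 3 arrays. In each of these genes the saline and IL-6 values do not overlap, as the rule for naming them required.

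When every one of the 35556 probe sets was tested, 16 rose and 1 fell. Leaving out an array gave 45 higher genes without saline replicate 3, 46 without IL-6 replicate 1 and 46 without IL-6 replicate 3, and 3 lower genes without IL-6 replicate 1 and 4 without saline replicate 2. Among the higher genes named for their lists, leaving out any array but 1 ended the call of Mt1 (all but saline replicate 2, limma adjusted p up to 0.200), Nfkbiz (all but saline replicate 1, up to 0.135), Fas (all but IL-6 replicate 1, up to 0.154), Onecut1 (all but IL-6 replicate 2, up to 0.144) and S100a8 (all but IL-6 replicate 3, up to 0.128). The call of Hmox1 was lost without saline replicate 2 or 3 or IL-6 replicate 2 or 3 (limma adjusted p up to 0.106), and that of Iigp1 without saline replicate 3 or any IL-6 array (up to 0.0870). That of Irs2 was lost without IL-6 replicate 1 or 3 (limma adjusted p up to 0.101), and that of Cish without saline replicate 1 or 3 (up to 0.0580). For called list members outside the rule for named genes, lost calls were not tabulated gene by gene, so their stability is not shown. A robust variance prior with a trend ended the calls of Lcn2 (limma adjusted p = 0.058), Mt1, Serpina9, Prg4 and Wsb1, of which Prg4 and Wsb1 are named after their values were seen.

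Positive acute-phase proteins, plasma and cell proteins that the liver makes more of in inflammation, rose as a list. Of 33 measured members 9 rose and 24 did not pass the test, 22 rose adjusted over the list alone, and 32 had positive differences (camera adjusted p = 3.01e-36, adjusted p = 0.043 with an estimated correlation). Beside Saa2, Saa1, Steap4, Orm2 and Lcn2, the risers were Saa4 (1.40 ± 0.15), the metallothionein Mt1 (1.04 ± 0.17), the fibrinogen chain Fga (0.98 ± 0.12) and the protease inhibitor Serpina3n (0.95 ± 0.12). The other probe set of Fga had a difference of 1.39. Fgb, another fibrinogen chain, had a difference of 0.30 ± 0.07 (limma adjusted p = 0.252). Hamp, which encodes the iron hormone hepcidin, had 0.35 ± 0.09 (limma adjusted p = 0.353). Neither passed the threshold over all genes, and both were among the 22 that rose adjusted over the list alone. None of the 17 negative acute-phase and abundant secreted liver proteins passed, with Alb, which encodes albumin, at 0.03 ± 0.07 (camera adjusted p = 0.276 for the list).

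The JAK-STAT list, which holds the signalling chain of IL-6 and its feedback genes, rose with 8 of 30 members called and 13 adjusted over the list alone (camera adjusted p = 4.45e-19, adjusted p = 0.043 with an estimated correlation). Among the called members were Socs3, Pim1, Cish (1.22 ± 0.16), Bcl3 (1.18 ± 0.08), Irf1 (1.07 ± 0.11), Socs2 (0.86 ± 0.13) and Pim3 (0.70 ± 0.08). The other probe set of Socs2 had a difference of 1.41. That of Irf1 had a difference of 0.02, and these data do not show which Irf1 probe set reports the gene. Stat3 itself rose by 0.52 ± 0.09 with a limma adjusted p of 0.04996, at the edge of the threshold, and the call was lost on leaving out any array but IL-6 replicate 2 (limma adjusted p from 0.0117 to 0.220 over the alternatives). The receptor genes Il6ra (-0.20 ± 0.10) and Il6st (0.29 ± 0.08) did not pass over all genes. Il6st was among the 13 that rose adjusted over the list alone, and Il6ra was not.

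Immediate-early transcription factors and feedback genes rose as a list, with 8 of 34 members called and, adjusted over the list alone, 14 higher and 1 lower (camera adjusted p = 1.32e-13, adjusted p = 0.043 with an estimated correlation). The called members were Gadd45a, Gadd45g, Zfp36, Egr1 (1.36 ± 0.14), Jun (1.32 ± 0.13), Btg2 (1.11 ± 0.15), Junb (1.07 ± 0.10) and Atf3 (0.58 ± 0.09). Of the interferon-responsive list, 3 of 25 members rose, Mx2, Irf1 and the GTPase gene Iigp1 (0.66 ± 0.09), and 8 rose and 1 fell adjusted over the list alone (camera adjusted p = 2.91e-09, adjusted p = 0.043 with an estimated correlation).

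In all, 11 of 34 lists passed at the preset correlation, 9 higher and 2 lower, and the 4 lists named so far passed with an estimated correlation. The preset test also called 3 to 8 lists in each of the 9 other splits of these 6 arrays into 3 and 3. With an estimated correlation, a check added after seeing the data, none of those splits called a list. Each of those splits has saline and IL-6 arrays on both sides. Part of the IL-6 difference therefore stays in the comparison and the rest enters the spread, so neither count measures false calls. The 7 lists that follow lost their call with an estimated correlation. With fry, the iron regulation, circadian, gluconeogenesis, Kupffer cell and cholangiocyte lists lost it too. On ranks, the metal and oxidative stress, iron regulation, gluconeogenesis and cholangiocyte lists did. Leaving out both arrays set apart by the second principal component ended the iron regulation and gluconeogenesis calls.

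The apoptosis and cell survival list was higher with 1 of 20 members called, the death receptor gene Fas (0.55 ± 0.09), and 3 adjusted over the list alone (camera adjusted p = 0.000536, adjusted p = 0.0855 with an estimated correlation). The metal and oxidative stress list was higher with 3 of 20 called, Mt1, the heme oxygenase gene Hmox1 (0.85 ± 0.12) and the zinc and iron transporter gene Slc39a14 (0.82 ± 0.09), and 5 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00244, adjusted p = 0.104 with an estimated correlation). Mt2 had a difference of 1.46 ± 0.29 that missed the threshold over all genes (limma adjusted p = 0.103) but was among the 5 higher over the list alone. The iron regulation list was higher with 3 of 28 called, Id3 (1.02 ± 0.12), Hmox1 and Slc39a14, and 6 adjusted over the list alone (camera adjusted p = 0.0209, adjusted p = 0.474 with an estimated correlation). That call was also lost without saline replicate 2, without IL-6 replicate 3 and when quantile normalization was applied again.

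The circadian clock list was lower by camera with a median difference of -0.13 over 20 members, yet its 2 called members, Nfil3 (1.22 ± 0.08) and Bhlhe40 (1.00 ± 0.12), which encode transcriptional repressors, rose. Adjusted over the list alone 2 rose and 4 fell (camera adjusted p = 0.00524, adjusted p = 0.536 with an estimated correlation), and the call was lost without saline replicate 2 and without IL-6 replicate 2. Relative to the saline mean, the circadian members averaged -0.27 in IL-6 replicate 2. They averaged -0.04 in IL-6 replicate 1 and -0.008 in IL-6 replicate 3, above saline replicate 1 at -0.09, so the groups overlapped. The gluconeogenesis and fasting glucose list was lower with 0 of 30 members called in limma and 1 lower adjusted over the list alone (camera adjusted p = 0.0419, adjusted p = 0.598 with an estimated correlation), a call lost without saline replicate 2, IL-6 replicate 1 or IL-6 replicate 2. Pck1 and G6pc, which encode enzymes of glucose production, had differences of -0.12 ± 0.08 and -0.34 ± 0.11, and Ppargc1a, a coactivator of fasting genes, -0.17 ± 0.09. None of these passed.

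**Figure D3:**
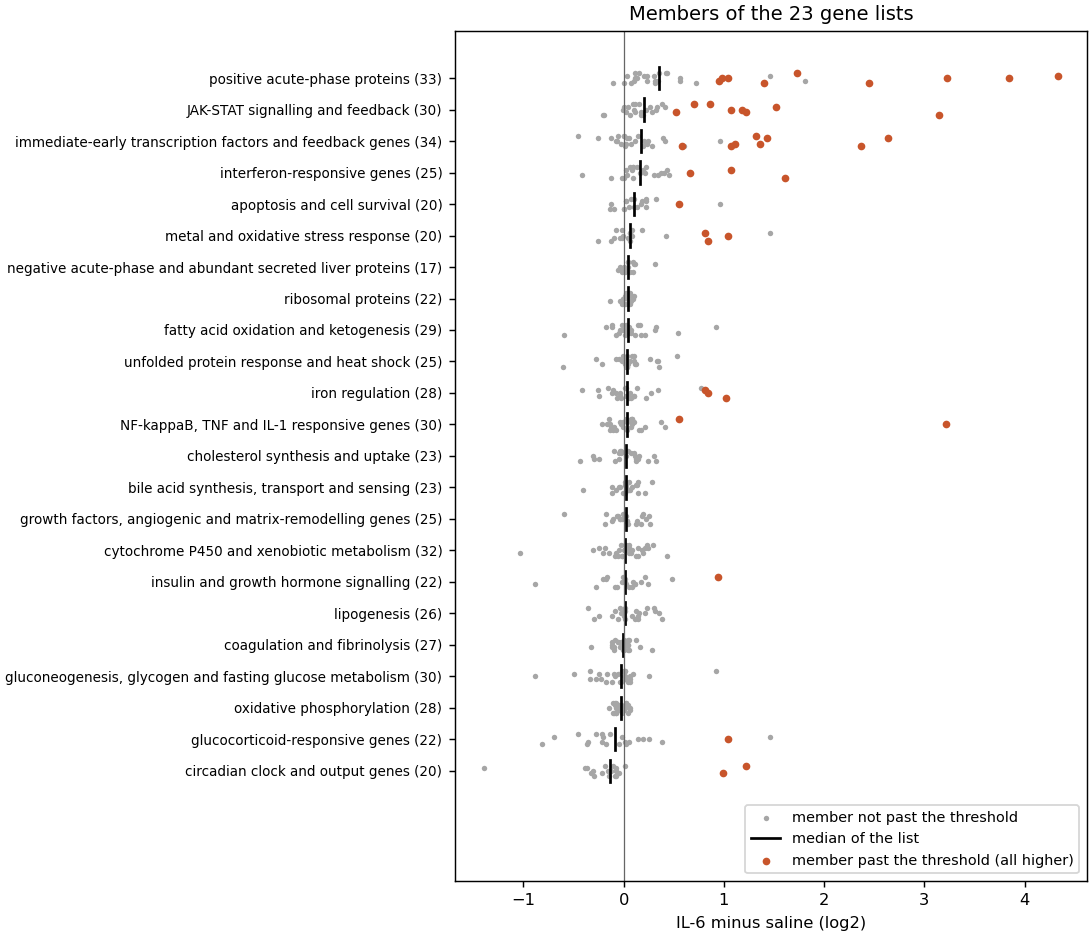
Log2 difference, IL-6 minus saline, of each measured member of the 23 gene lists, with the number of members in parentheses, a black line for the list's median and larger coloured points for members past the threshold. Medians run from 0.35 for positive acute-phase proteins to -0.13 for the circadian list.

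Among metabolic lists, insulin and growth hormone signalling held 1 called gene of 22, Irs2, an adaptor of the insulin receptor, at 0.94 ± 0.13 (limma adjusted p = 0.0151). Adjusted over that list alone 1 rose and 2 fell, and the list did not pass (camera adjusted p = 0.502). Irs1 (-0.21 ± 0.12) and Igfbp1 (0.48 ± 0.18) did not pass. No member was called in fatty acid oxidation and ketogenesis (0 of 29, camera adjusted p = 0.190), lipogenesis (0 of 26, 0.190), cholesterol synthesis and uptake (0 of 23, 0.694), bile acid synthesis, transport and sensing (0 of 23, 0.419), or cytochrome P450 and xenobiotic metabolism (0 of 32, 0.366). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had a difference of -0.03 ± 0.20. The limma counts of 0 stand beside 84 called genes of all 19938, so a 0 in a list of this size says little. At the looser unadjusted limma p under 0.05, 1319 of all genes passed, 754 higher and 565 lower.

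The NF-kappaB, TNF and IL-1 list held 2 called genes of 30, Cxcl1 and Nfkbiz (0.55 ± 0.08), with 3 adjusted over the list alone (camera adjusted p = 0.0642). The glucocorticoid-responsive list held 1 of 22, Mt1, with 3 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.118). The unfolded protein response and heat shock list had 0 of 25 called, with 2 adjusted over the list alone (0.149). Coagulation and fibrinolysis (0 of 27, 0.762), growth factors and matrix remodelling (0 of 25, 0.502), ribosomal proteins (0 of 22, 0.276) and oxidative phosphorylation (0 of 28, 0.145) did not pass.

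Few markers of other cell types in the liver passed the test. The Kupffer cell and macrophage markers were higher by camera, with 14 of 15 differences positive, a median of 0.10 and 0 called in limma (camera adjusted p = 0.0146, adjusted p = 0.622 with an estimated correlation). The call was lost without saline replicate 3 or IL-6 replicate 2. Relative to the saline mean, the markers averaged 0.28 in IL-6 replicate 2. They averaged 0.02 in IL-6 replicate 1 and 0.03 in IL-6 replicate 3, below saline replicate 1 at 0.08, so the groups overlapped. The cholangiocyte markers were higher with 1 of 9 called, Onecut1 (0.64 ± 0.10), a transcription factor gene that hepatocytes also express, and 2 adjusted over the list alone (camera adjusted p = 0.0209, adjusted p = 0.332 with an estimated correlation). That call was lost without saline replicate 1, saline replicate 2 or IL-6 replicate 1. Neutrophil markers held 2 called genes of 15, Lcn2 and S100a8 (0.65 ± 0.09 at a saline level of 3.60, below the 25th percentile), and did not pass as a list (camera adjusted p = 0.190). Hepatocytes (camera adjusted p = 0.405), endothelial cells (0.350), stellate cells and fibroblasts (0.230), B cells (0.987), T and NK cells (0.154), erythroid cells (0.762), pancreatic acinar cells (0.687) and adipocytes (0.154) did not pass and held no called gene.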

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

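A probe set that the comparisons of genes leave out, because the platform table used here gives it no gene name, stood above the saline arrays. Probe set 10563608 went from 5.28 ± 0.06 to 6.07 ± 0.06 (SD, n = 3), a log2 difference of 0.79 (limma adjusted p = 0.0397 over all 35556 probe sets). Probe set 10344145, also unnamed here, had a log2 difference of -1.18 (limma adjusted p = 0.0181), from a saline level of 3.91 to 2.72 after IL-6. Both levels lie below the 25th percentile of all genes (4.59), where differences are hard to separate from background. No explanation was tested for either.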

How the results depend on the processing

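In place of the 77 higher and 7 lower genes, 16 probe sets rose and 1 fell when every probe set was tested. The 1 that fell was the unnamed 10344145, so none of the 7 lower genes kept its call, and the 16 include the unnamed 10563608. With a trend of the prior variance added to that, an alternative chosen after seeing the data, 36 rose and 3 fell. The prior degrees of freedom were 2.56 over all probe sets and 5.28 over genes, and 35556 tests were adjusted for in place of 19938. With every probe set of 1 symbol, also chosen after seeing the data, 77 rose and 6 fell. A threshold of 0.1 gave 12 lower genes and 97 higher, and a requirement of 2-fold gave 32 and 2, by construction. Leaving out each array gave 45 to 67 higher and 3 to 5 lower genes and kept 48 to 66 of the 84, with fewer arrays tested. The other scalings, filters, priors and array weights gave 80 to 104 higher and 7 to 9 lower genes. Arrays of the same number deviated from their group means with correlations of 0.076, -0.116 and -0.087, so no shared deviation was visible. Too few arrays were run to tell whether the numbers pair them. The highest of the 9 pairs was saline replicate 2 with IL-6 replicate 3, at 0.185. Leaving out both of these, chosen after seeing the data, gave 31 higher and 2 lower genes, with fewer arrays tested, and 11 lists, 9 of them among the 11 reported. The fit with the replicate number as a block gave 59 and 6 and kept 62 of the 84. Of 34 lists, 11 passed as reported, 4 with an estimated correlation, 6 with fry and 7 on ranks, and 8 to 14 when an array was left out. The cause was not tested. Of 39 called genes among the 147 named, 19 kept the call under all alternatives fixed beforehand and run on genes. None of those 39 changed sign, and 15 sign changes among the 147 were all in genes not called. Signs were not tabulated for the other called genes. S100a8 and Olfr960 lie below the 25th percentile of level, where signal over background is the limit.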

Other observations

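Several called genes stood outside the lists, 46 of the 84, and are named here after their values were seen. They included the zinc finger gene Zfp36l1 (1.03 ± 0.13), the ARID genes Arid5b (0.89 ± 0.10) and Arid5a (0.78 ± 0.11), the magnesium transporter genes Slc41a2 (0.99 ± 0.17) and Slc41a1 (0.72 ± 0.11), the receptor gene Il17ra (0.81 ± 0.08), the adaptor gene Myd88 (0.67 ± 0.09), the transcription factor gene Gata6 (0.81 ± 0.09), and Zc3h12a (0.47 ± 0.08), which encodes an RNase that degrades cytokine mRNAs. Of 873 symbol families of at least 4 measured genes, a grouping tried after seeing the calls, Saa held 3 higher genes of 4 (one-sided Fisher's exact test, adjusted p = 0.000193) and Gadd 2 of 4 (adjusted p = 0.0384). Members of a family can share probe signal.

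Among transcripts lying inside another gene, also looked up afterwards, Gdap10 rose by 0.81 ± 0.12 while the surrounding Nampt had 0.19 ± 0.09, and Eid3 rose by 0.78 ± 0.08 while Txnrd1 had 0.19 ± 0.07. 2900005J15Rik fell by 0.66 ± 0.08 within Prkag2 (0.02 ± 0.09). Gpr146 and the surrounding 3110082I17Rik had similar differences, 0.45 ± 0.08 and 0.42 ± 0.08, and only the first passed the threshold (limma adjusted p = 0.105 for the other). These differences between neighbours were not tested.

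In the 10 splits of the 6 arrays into 3 and 3, the real split gave 77 and 7 genes and the highest other gave 0, and for lists 11 against 8. In each case 1 split, the real one, gave as many, and 10 splits are too few for a share under 0.05. The other splits also mix saline and IL-6 arrays on each side. That puts the IL-6 difference into the spread, so few gene calls there were likely in advance.

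The 5 tests of explanations that follow were chosen after the results were seen. They replaced 2 others, also run afterwards, that asked whether saline replicate 2 or time of day lay behind 8 lower glucocorticoid and clock genes. Those 8 had been picked for being lower, so the tests decided nothing and were set aside: their mean difference was -0.58 ± 0.16, it was -0.43 ± 0.07 without saline replicate 2, and 7 clock output genes had -0.17 ± 0.13.

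Immediate-early genes such as Egr1 and Jun also respond to handling of animals or tissue, which may differ between groups. A set of 10 handling-sensitive genes, Fos among them, had a mean log2 difference of -0.0374 (95% interval -0.19 to 0.12), below the smallest called change of 0.58. The set was assembled after the values were seen and left out 8 called members of the immediate-early list, so it excludes nothing, and handling stays open beside IL-6 itself.

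Higher Lcn2 and S100a8 could come from more neutrophils in the liver or from liver cells. The 5 other neutrophil markers above the 25th percentile of level had a mean difference of -0.0364 (95% interval -0.39 to 0.31), and S100a9 had -0.01 at a saline level of 4.56. The first set left out the called S100a8, its bound of 0.43 was set afterwards, and S100a9 lies below the 25th percentile of level. Neither source is excluded.

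The small nucleolar RNAs Snord14e (0.98 ± 0.11) and Snora31 (0.58 ± 0.08) rose while the genes whose introns hold them, Hspa8 and Tpt1, had a mean difference of -2.2e-05 (95% interval -0.17 to 0.17). Both host probe sets lie in the brightest 1% of genes, at mean levels of 12.11 and 11.45. Array values ran to 14.1, and Serpina3n still rose from 11.33 to 12.28, so these levels were not a ceiling of the scale. Saturation of the host probe sets themselves was not assessed. Unless the host probe sets were saturated, the interval argues against a rise of these host mRNAs by 0.39, 50% of the mean rise of Snord14e and Snora31. That bound was set after the results were seen. A condition on brightness, changed more than once after the values were seen, left the test itself undecided. A shift of small nucleolar RNAs in general, as from unequal recovery of small RNA, may contribute: the 51 others had a mean difference of 0.167 (95% interval -0.03 to 0.36), 39 of them positive, with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 can give, and a camera p of 0.0888 with an estimated correlation. That test was written once their median was known, and its first form, 2 standard errors in place of the 95% interval, would have put the mean above 0. The general shift stays open. The values of Hspa8 and Tpt1 argue against a host rise of the size given above only if their probe sets were not saturated.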
